A study of Mus musculus with 4 samples.

How the data were processed

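Ribosome-protected fragments were sequenced from mouse bone-marrow-derived monocytes after 3 days of RANKL, with 2 libraries of the Nat10 conditional knockout and 2 of wild type. Per the labels' protocols, cells were washed in cycloheximide, which stalls ribosomes on mRNA, ribosomal RNA was depleted, and libraries were made with a small-RNA kit. The authors deposited raw counts per gene, per the file headers, as whole numbers in 1 table with coordinates, gene types and pathway annotation. The submitters' processing notes name fastp, Bowtie, STAR and HTSeq and the genome build GRCm39 (mm39), with no versions, roles or order. Whether only coding-sequence reads or certain footprint lengths were counted, how duplicates and molecular identifiers were handled, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Reads from PCR are not independent molecules, so counting intervals cover counting error only. Counts of gene families and of genes with near-identical copies or pseudogenes are uncertain because the treatment of reads that match several genes is unknown. Among the genes named, this concerns ribosomal protein, histone, Ifit, Gbp, class II, Cxcl and lysozyme genes and Fth1. Overlapping and antisense genes cannot be told apart without the strand setting.

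The table held 22417 genes, 22401 of them with a symbol and 12461 with at least 1 count, nearly all protein-coding, so totals are those of the listed genes and not of the whole libraries. They were 1467611, 1481083, 906937 and 3014620 for cKO replicates 1 and 2 and WT replicates 1 and 2. Column names matched sample descriptions, and the count column of each sample was used. Any columns beyond these were not checked for further per-sample values. No library was a copy of another, since each pair differed by more than sampling noise in a chi-square test. Library complexity was described by the genes with a count, by the number expected after thinning to the smallest total (10171, 10376, 10637 and 8832, in the order above) and by the genes at 0 where at least 20 counts were expected from the other libraries. A gene with no count was bounded by a floor of 3 counts over the group, and no member of a tested list was at 0 in a whole group. Ratios of genes with 1 to 3 counts in a group were computed from summed counts with exact 95% binomial intervals.

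Differences were tested with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM factors and fitted by the quasi-likelihood method with robust estimation and genotype as the only term. P-values were adjusted by Benjamini-Hochberg over the 7953 genes tested, at a threshold of 0.05. All log2 fold changes are cKO minus WT, standard errors come from the fitted model, and CPM values use TMM-scaled totals. The common biological coefficient of variation was 0.448, and the median log2 fold change of all genes was -0.01. The replicate numbers showed no sign of pairing the samples, and the fit with them as a block is an alternative. The design, the alternatives and 30 gene lists were fixed before the data were examined. The lists cover osteoclast function, RANK signalling and its regulators, V-ATPase, lysosome, fusion, podosomes, macrophage, interferon, inflammation, ac4C and nucleolus, translation, ribosome, metabolism, cell cycle, histones, stress, p53, iron and redox, and markers of other cell types and sex. The 25 lists with at least 5 tested members were tested with camera (limma 3.58.1, inter-gene correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the lists. At this preset correlation camera's p-values rest on the number of genes and not on that of libraries. With an estimated correlation its degrees of freedom come from the 4 libraries, so few lists can pass and a miss says little. For each list the members past the threshold were also counted after adjustment over the list alone.

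Genes were named by a rule fixed before the data were examined. It took Nat10 and Nfatc1, the 10 largest changes in each direction among genes past the threshold with an average log2 CPM of at least 4 and groups that do not overlap, leaving out predicted genes and pseudogenes, up to 4 members of each list that passed (or the 2 with the smallest p), and sex-linked genes. Other genes are marked as named after their values were seen. All 111 genes past the threshold had groups that did not overlap.

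The pipeline was tested on simulated counts of the 7953 genes with 200 changed genes in each of 5 runs. With the fitted spread it called 12.1%, 48.2% and 72.2% of genes changed by 1, 2 and 3 on the log2 scale, and 3.28% of its calls were false. With WT replicate 2 made noisier, it called 0.310%, 26.0% and 53.5%, with 0 false calls among 251. This noisier simulation was written after a first version, which gave each library 1 spread at all abundances, had called 0 genes of any size; both were kept. The set test found 10 of 10 lists shifted by 0.5 and called 1 of 10 unshifted lists. That was 1 run with the fitted spread and genes drawn independently, so it does not cover correlated genes or a noisier WT replicate 2.

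Alternatives fixed before the data were examined were RLE, upper-quartile or library-size scaling, no filter or a CPM of at least 1 in all libraries (planned as a stricter filter, but it also kept genes that the main filter dropped, so it is a different one), DESeq2 1.42.0, limma-voom, edgeR's exact test, edgeR without robust estimation, protein-coding genes only, removal of mitochondrial, histone and hemoglobin genes, the replicate block, each library left out in turn, an adjusted p under 0.1, a test against a fold of 1.5, and for lists an estimated correlation, ranks and fry. Thinning to the smallest library and limma-voom with library quality weights were added after the data had been seen. Pathways of the deposited annotation with 10 to 300 tested genes were tested with camera, also after the data had been seen.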

Results

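Ribosome profiling sequences the short stretches of mRNA that ribosomes protect from nuclease, so a gene's count reflects both how much of its mRNA is present and how often it is being translated. Counts were compared between bone-marrow-derived monocytes of wild-type (WT) mice and of mice with a conditional knockout (cKO) of Nat10, the enzyme that acetylates cytidine in RNA to N4-acetylcytidine (ac4C). All cells had been driven towards osteoclasts, the bone-resorbing cells of the monocyte lineage, with the cytokine RANKL for 3 days. There were 2 libraries labelled Nat10 cKO and 2 labelled WT, and the question was what the loss of Nat10 does to translated mRNA during osteoclast formation, with Nfatc1, the master transcription factor of osteoclasts, named in the series title. Matched RNA-seq was not used here, so a change in counts cannot be assigned to mRNA level or to translation. The libraries held 1467611 and 1481083 counts (cKO replicates 1 and 2) and 906937 and 3014620 counts (WT replicates 1 and 2) over 22417 genes, of which 7953 had enough counts to be tested. The labels do not say that replicates came from separate mice or cultures, so p-values of single genes measure only the spread between these samples, which may be technical. The p-values of lists and pathways by camera at a preset correlation compare genes with other genes. They do not measure how a list varies between samples.

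The 4 libraries were not alike in quality. The cKO pair was close, with a coefficient of variation of 0.247 between libraries beyond counting noise, and the WT pair was not, at 0.578. The libraries did not group by genotype: WT replicate 1 was closer to the cKO libraries (0.387 and 0.361; correlation of log2 CPM 0.862 and 0.876) than to WT replicate 2 (correlation 0.797), which lay far from the cKO libraries too (0.672 and 0.657). WT replicate 2 had the most counts and the fewest genes with a count, 9402 against 10508 to 10798 in the other libraries. In WT replicate 2, 362 of the 7794 genes for which at least 20 counts were expected from the other libraries had none, against 1 of 5060 in WT replicate 1, 45 of 6301 in cKO replicate 1 and 32 of 6311 in cKO replicate 2. The Y-linked gene Uty had 84 counts in WT replicate 2 and none elsewhere, while Kdm5d, Ddx3y and Eif2s3y had none in any library. Saa3, an acute-phase gene of macrophages, made up 4.12% to 5.13% of the counts in every library.

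Nat10 itself was not measurably lower in the libraries labelled cKO. Nat10 (ENSMUSG00000027185, chromosome 2, 103551601 to 103591615, minus strand, GRCm39) had 101 and 72 counts in the cKO libraries and 77 and 148 in the WT libraries. These are 58.9 ± 14.7 CPM (library-scaled counts; SD, n = 2) against 67.8 ± 24.2 (SD, n = 2), a log2 fold change of -0.18 with a standard error (SE) of 0.41 and a 95% interval from -1.11 to 0.74 (adjusted p = 0.907, edgeR quasi-likelihood test). The sign was not stable, since it turned to 0.06 without cKO replicate 2 and to 0.25 without WT replicate 1. Counts over the whole gene do not show whether a deleted exon is missing, and which part of the gene the knockout removes is not given in the sources used here. Every direction below is therefore a difference between libraries by their genotype label, which the Nat10 counts do not check.

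Nfatc1 was lower in both cKO libraries than in either WT library. Nfatc1 (ENSMUSG00000033016, chromosome 18, 80649420 to 80756286, minus strand) stood at 82.6 ± 0.43 CPM in cKO and 186 ± 10.7 CPM in WT (SD, n = 2 each), from 120 and 123 against 162 and 565 counts. The log2 fold change was -1.17 (SE 0.26), with an adjusted p of 0.0736 over all genes tested by edgeR, which missed the threshold of 0.05, and of 0.0222 adjusted over the list alone, that of RANK signalling genes. The fold hardly moved without single libraries, but the adjusted p ranged from 0.000141 without WT replicate 1 to 0.679 without cKO replicate 1.

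In all, 51 genes were higher and 60 lower in the libraries labelled Nat10 cKO at an adjusted p under 0.05 (edgeR), out of 965 with an unadjusted p under 0.05. The genes that rose most were Cxcl1, Ifit2, Il6, Gbp5, Il1b, the class II gene H2-Aa, the VEGF receptor gene Kdr, Il1a, Cxcl2 and H2-M2, with log2 fold changes from 5.80 down to 2.82. Cxcl1 (4.41 and 1.03 CPM in WT replicates 1 and 2), Ifit2 (13.2 and 2.06), Il6 (16.5 and 2.06) and Gbp5 (46.3 and 5.14) were much lower in WT replicate 2. The size of their folds thus leans on that library. The other risers named here differed less between the WT libraries. The genes that fell most were largely those of the extracellular matrix: Col2a1, the scaffold protein gene Akap12, Tnn, Col1a1, the collagen chaperone gene Fkbp10, Col6a2, Col3a1, Bgn, Thbs2 and Col1a2, with log2 fold changes from -6.50 to -3.08. All 51 and all 60 kept their direction when any one library was left out. This was all but fixed in advance, since the groups did not overlap for any of the 111 genes. The count depended on which libraries were used: without WT replicate 2, 250 genes were higher and 217 lower, and without WT replicate 1, 1354 and 1066, in each case with all 111 among them and with the spread taken from the cKO pair alone. Without cKO replicate 1, 35 were higher and 38 lower, of which 34 and 33 were among the 111, and without cKO replicate 2 there were 40 and 42. Some calls lay close to the threshold: Gbp5, Akap12, Actn1, Rrm2, Tfrc and Fth1 missed it under at least 1 other scaling of the libraries, Col2a1, Akap12 and Gbp5 with DESeq2, Col2a1, Akap12, Tnn, Fkbp10, Col6a2, Thbs2 and Lyz2 with limma-voom, and Il6 and Gbp5 with the replicate number as a block.

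**Figure D1:**
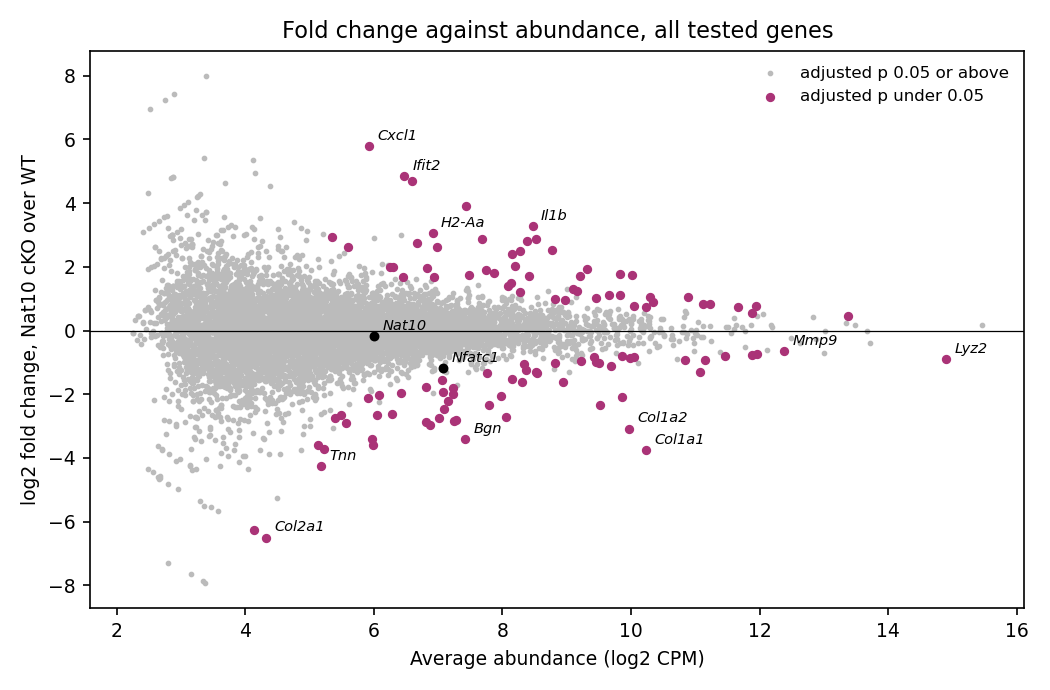
Log2 fold change of the libraries labelled Nat10 cKO over WT (vertical axis) against average abundance in log2 CPM (horizontal axis) for the 7953 tested genes; coloured points are the 111 genes with an adjusted p under 0.05. Cytokine genes such as Il1b lie at the top and collagen genes such as Col1a1 (log2 fold change -3.75) at the bottom, while Nat10 and Nfatc1 (black) are not among the coloured points.

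Inflammatory cytokines and chemokines were higher in the libraries labelled cKO. Il1b, the gene of interleukin-1 beta, rose from 67.2 ± 11.1 CPM in WT to 639 ± 27.7 CPM in cKO (SD, n = 2 each), a 9.64-fold rise (log2 3.27, SE 0.21, adjusted p = 0.000307, edgeR). Cxcl2, a neutrophil-attracting chemokine gene, rose 7.38-fold (log2 2.88, SE 0.19) from 87.6 to 649 CPM. Tnf rose 5.67-fold (log2 2.50, SE 0.20), from 92.8 ± 0.21 to 526 ± 50.8 CPM, and Ccl3 rose 3.37-fold (log2 1.75, SE 0.14). Cxcl1 had 4 and 3 counts in the WT libraries, so its 55.5-fold rise rests on few WT counts. Of the 23 tested members of the list, 10 rose, 1 fell and 12 did not pass; adjusted over the list alone, 12 rose and 2 fell. The member that fell was Spp1, the gene of osteopontin, a bone matrix phosphoprotein that osteoclasts also make (log2 -1.29, SE 0.14; named after its values were seen). The list's median log2 fold change was 1.70, with an adjusted p of 2.74e-26 by limma's camera test at a preset correlation and an adjusted p = 0.212 with an estimated correlation. Without WT replicate 2, 12 members rose and 1 fell. The stromal and osteoblast markers moved the other way between the same libraries, with a median 4.43 times higher in WT. Il6 missed the threshold without cKO replicate 1 (log2 4.93, adjusted p = 0.0620, edgeR).

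Interferon-stimulated genes were also higher. Gbp2, a guanylate-binding protein gene, rose 5.78-fold (log2 2.53, SE 0.21), Isg15, a ubiquitin-like modifier gene, rose 3.85-fold from 264 ± 98.5 to 1007 ± 48.4 CPM (SD, n = 2 each), and Ifit1 rose 3.77-fold from 89.2 ± 2.90 to 337 ± 0.20 CPM. Ifit2 rose 28.6-fold (log2 4.84, SE 0.66, adjusted p = 0.01003, edgeR) from 12 and 6 counts in the WT libraries. These are 13.2 CPM in WT replicate 1 and 2.06 CPM in WT replicate 2, so the size of the fold leans on WT replicate 2. Of 26 tested members, 8 rose and none fell, and 17 rose when adjusted over the list alone. The median log2 fold change was 1.14 (adjusted p = 4.83e-24 by camera, and adjusted p = 0.212 with an estimated correlation), and 17 members rose without WT replicate 2. Between the same libraries the stromal markers and the macrophage genes Csf1r and Lyz2 were lower in cKO. Gbp5, which rose in the 4-library test (log2 3.90, SE 0.75), had an adjusted p of 0.9999 when either cKO replicate was left out, by edgeR.

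Of the 6 tested members of the dendritic cell and antigen presentation list, 2 rose, both of MHC class II presentation. H2-Aa, a class II alpha chain gene, rose 8.36-fold (log2 3.06, SE 0.32), from 25.6 ± 1.26 to 213 ± 47.4 CPM, and Cd74, the invariant chain gene, rose 4.06-fold (log2 2.02, SE 0.22), from 115 ± 22.2 to 472 ± 48.5 CPM (SD, n = 2 each). Adjusted over the list alone, 4 rose and 1 fell. The one that fell there was Itgax, the gene of the dendritic cell integrin CD11c (log2 -0.82, SE 0.33; named after its values were seen). The list's median log2 fold change was 1.56 (adjusted p = 1.93e-06 by camera, and adjusted p = 0.257 with an estimated correlation), and the camera call was lost without WT replicate 1 (adjusted p = 0.176). Without WT replicate 2, 4 of 7 members rose. Stromal markers were lower in these libraries. Kdr missed the threshold without cKO replicate 2 (log2 2.50, adjusted p = 0.624, edgeR).

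**Figure D2:**
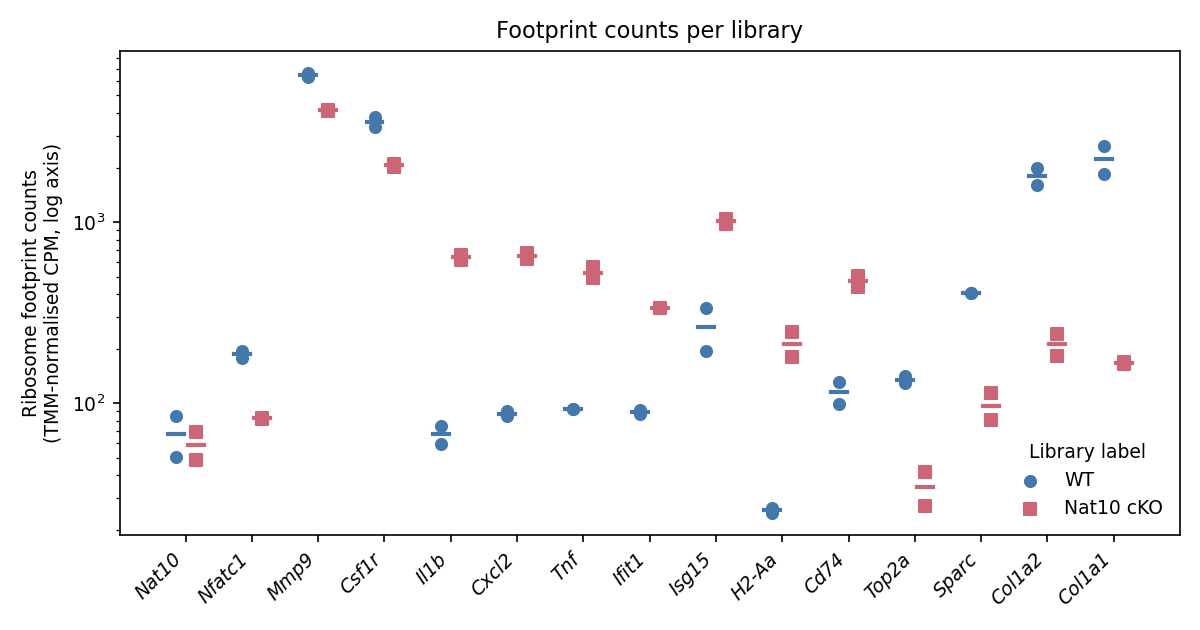
Normalised footprint counts (CPM, log axis) of 15 genes in each library, circles for the 2 WT and squares for the 2 Nat10 cKO libraries, with bars at the group means. Il1b lies at 59.3 and 75.0 CPM in WT and at 619 and 659 in cKO, Col1a1 at 1838 and 2632 in WT and at 164 and 169 in cKO, and the Nat10 values of the groups overlap.

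Stromal and osteoblast genes, chiefly collagens and other matrix proteins, were lower in the libraries labelled cKO. Col1a1, a chain of type I collagen, fell 13.4-fold, from 2235 ± 561 CPM in WT to 167 ± 3.00 CPM in cKO (SD, n = 2 each; log2 -3.75, SE 0.20, adjusted p = 0.000198, edgeR), the smallest p of all genes tested. Col1a2, its partner chain, was 8.43 times higher in WT (1784 ± 273 against 212 ± 42.0 CPM), Bgn, the gene of the matrix proteoglycan biglycan, 10.7 times and Sparc, the gene of osteonectin, 4.19 times. Of 10 tested members, 7 fell and none rose, 8 fell when adjusted over the list alone, and 8 of 11 fell without WT replicate 2. The 2 members with a positive log2 fold change, neither past the test, encode no matrix protein: the growth factor receptor gene Pdgfrb (34 and 19 counts in cKO, 8 and 5 in WT) and the transcription factor gene Runx2 (13 and 19 against 4 and 0), named after their values were seen. The median log2 fold change was -2.15 (adjusted p = 4.61e-30 by camera, and adjusted p = 0.165 with an estimated correlation). The list was fixed as markers of other cell types that a bone marrow culture can hold, and its summed level was 642 and 679 CPM in cKO and 4684 and 5943 CPM in WT. Col2a1 and Akap12 each had 1 count in the cKO libraries together, so their ratios are loosely bounded. Col2a1 was 113 times higher in WT (counting interval 19.99 to 4498) and Akap12 106 times (18.7 to 4225). Col2a1 missed the threshold without cKO replicate 1 (adjusted p = 0.0841), Akap12 without cKO replicate 1 (0.0620) and without cKO replicate 2 (0.176), and Fkbp10 (0.0689) and Col6a2 (0.0809) without cKO replicate 2, all by edgeR.

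The fixed list of osteoclast effector genes was modestly lower. Mmp9, the gene of a matrix metalloproteinase that osteoclasts secrete, fell from 6501 ± 236 CPM in WT to 4134 ± 23.8 CPM in cKO (SD, n = 2 each; log2 -0.65, SE 0.10, adjusted p = 0.0130, edgeR). It was the only one of 19 tested members to pass, and 6 fell when adjusted over the list alone. Named after their values were seen, these included Ctsk, the gene of cathepsin K that degrades bone collagen (log2 -0.65, SE 0.13), and Acp5, that of tartrate-resistant acid phosphatase (log2 -0.66, SE 0.16), which did not pass over all genes (adjusted p = 0.0507 and 0.110). The median of the list was -0.56 (adjusted p = 0.00176 by camera, and adjusted p = 0.257 with an estimated correlation), and 5 members fell without WT replicate 2. The wider Osteoclast differentiation pathway of the deposited annotation, tested after the data had been seen, was not lower (81 tested, median 0.12, 4 rose, 2 fell, adjusted p = 0.317 by camera). The stromal markers were lower in the same libraries, and the WT pair was the less alike of the pairs. Mmp9 missed the threshold without cKO replicate 1 (adjusted p = 0.0676).

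The list of RANK signalling genes and osteoclast transcription factors did not pass the set test (30 tested, median log2 fold change -0.37, adjusted p = 0.137 by camera), and without WT replicate 2 its median was -0.02, with 1 member higher and 3 lower (adjusted p = 0.246). Csf1r, the receptor gene for M-CSF, which keeps osteoclast precursors alive, was its 1 member that fell (log2 -0.80, SE 0.11), from 3574 ± 303 to 2054 ± 67.5 CPM (SD, n = 2 each), and adjusted over the list alone 2 fell, Csf1r and Nfatc1. Among 15 negative regulators of osteoclast formation, Tnfaip3, the gene of the NF-kappa-B inhibitor A20, rose 3.31-fold (log2 1.73, SE 0.19) and the other 14 did not pass (median 0.16, adjusted p = 0.138 by camera); adjusted over the list alone 1 rose, and without WT replicate 2, 3 rose (median 0.44, adjusted p = 0.0536). Of 17 cell fusion genes, Adam8 (log2 -1.33, SE 0.19) and Cd36 (log2 -0.85, SE 0.14) fell, and 4 fell and 1 rose when adjusted over the list alone (median -0.01, adjusted p = 0.142). Gsn, the gene of the actin-severing protein gelsolin (log2 -0.98, SE 0.17), and Actn1, that of alpha-actinin (log2 -1.06, SE 0.20), were the 2 of 28 podosome and adhesion genes that fell, over all genes and adjusted over the list alone. The podosome list's median was -0.28 (adjusted p = 0.0221 by camera, adjusted p = 0.456 with an estimated correlation), and the call was lost without WT replicate 2 (median -0.03, adjusted p = 0.360), without cKO replicate 2 (adjusted p = 0.113) and with a filter on CPM in all libraries (adjusted p = 0.0700). No V-ATPase subunit of 18 tested passed (median 0.03, adjusted p = 0.643; 1 rose and 4 fell without WT replicate 2), and Ctsz, a cathepsin gene, was the 1 of 27 lysosomal genes that rose (log2 0.75, SE 0.13; list median -0.08, adjusted p = 0.317), also when adjusted over the list alone. Without 1 of the cKO libraries, Cd36, Actn1, Gsn and Ctsz missed the threshold, with adjusted p-values up to 0.208 for Cd36, 0.447 for Actn1, 0.203 for Gsn and 0.0676 for Ctsz.

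Of 21 tested monocyte and macrophage genes, 3 fell: Csf1r, Lyz2, the lysozyme gene of macrophages (log2 -0.91, SE 0.14), and Trem2, a receptor gene of the macrophage lineage (log2 -1.55, SE 0.28). Adjusted over the list alone, 6 fell and 1 rose. The list's median was 0.09 while its mean was -0.01 and the camera test pointed down, without passing (adjusted p = 0.223), but the list passed fry (adjusted p = 0.0431); without WT replicate 2 the median was -0.14. Trem2 missed the threshold without cKO replicate 1 (adjusted p = 0.255) and without cKO replicate 2 (0.165). Lyz2 shares most of its sequence with Lyz1, so its counts are uncertain.

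Cell cycle genes were lower in the libraries labelled cKO, and all 27 tested members had a negative log2 fold change. Top2a, the gene of a DNA topoisomerase of dividing cells, fell 3.91-fold, from 135 ± 8.64 to 34.4 ± 10.5 CPM (SD, n = 2 each; log2 -1.97, SE 0.35, adjusted p = 0.0324, edgeR). Rrm2, a ribonucleotide reductase gene, fell from 75.0 ± 17.1 to 11.9 ± 5.43 CPM (log2 -2.65, SE 0.51, adjusted p = 0.0497). These 2 passed over all genes and adjusted over the list alone, the median was -1.60 (adjusted p = 5.26e-09 by camera, adjusted p = 0.212 with an estimated correlation), and 4 of 26 fell without WT replicate 2. Both missed the threshold without cKO replicate 1 (Top2a adjusted p = 0.0504, Rrm2 0.0636) and without cKO replicate 2 (Top2a 0.235, Rrm2 0.255). Of 19 replication-dependent histone genes, whose near-identical copies make their counts uncertain, 18 were negative and none passed, with 3 lower when adjusted over the list alone (median -1.45, adjusted p = 6.53e-05 by camera, adjusted p = 0.257 with an estimated correlation). The histone median ranged from -2.23 without cKO replicate 1 to -1.11 without cKO replicate 2. H2bc18 (log2 -1.84, SE 0.43) and H1f3 (log2 -2.88, SE 0.76) had the smallest p of these. The wider Cell cycle pathway of the deposited annotation, tested after the data had been seen, did not pass (91 tested, median -0.04, none fell, adjusted p = 0.829 by camera), while that of DNA replication was lower (30 tested, median -0.50, adjusted p = 0.0345 by camera, adjusted p = 0.529 with an estimated correlation). The stromal markers were lower in the same libraries.

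Among metabolic lists, glycolysis genes had a median of -0.29 (17 tested, none passed, 3 lower adjusted over the list alone, adjusted p = 0.00171 by camera, adjusted p = 0.308 with an estimated correlation), with Ldha at log2 -1.06 (SE 0.23) and Pkm at -0.51 (SE 0.15). Nuclear-encoded respiratory chain genes had a median of -0.19 (71 tested, none passed, 3 lower adjusted over the list alone, adjusted p = 0.0105 by camera, adjusted p = 0.257 with an estimated correlation), with Atp5a1 at -0.64 (SE 0.13) and Cox8a at -0.85 (SE 0.17), and that call was lost without cKO replicate 2 (adjusted p = 0.0907) and without WT replicate 1 (0.0854). The wider Oxidative phosphorylation pathway of the deposited annotation, tested after the data had been seen, did not pass (94 tested, median -0.14, none fell, adjusted p = 0.0996 by camera). Both lists were lower in the libraries in which the stromal markers were lower (median -2.15). Iron and redox genes did not pass as a list (21 tested, median 0.26, adjusted p = 0.137), but did without WT replicate 2 (adjusted p = 0.0115), without cKO replicate 1 (0.0362), with DESeq2 (0.0212) and with library quality weights (0.0270). Of its members, Sod2, the mitochondrial superoxide dismutase gene (log2 0.83, SE 0.11), Fth1, the ferritin heavy chain gene (log2 1.04, SE 0.19), and Gclm, of glutathione synthesis (log2 0.77, SE 0.14), rose, and Tfrc, the transferrin receptor gene (log2 -0.84, SE 0.16), fell; adjusted over the list alone 5 rose and 3 fell. Gclm missed the threshold without cKO replicate 1 (adjusted p = 0.116) and cKO replicate 2 (0.131), as did Tfrc (0.609 and 0.0610). Cholesterol and fatty acid synthesis genes had a median of -0.25 and none of 20 passed, over all genes or the list alone (adjusted p = 0.138; Scd2 -1.19, SE 0.28; Fasn -1.02, SE 0.30). The 7 tested mitochondrially encoded protein genes had a median of -0.27, with none past either threshold (adjusted p = 0.411; mt-Nd6 -0.66, SE 0.35; mt-Co1 -0.32, SE 0.19). Without WT replicate 2 that list passed (median -0.39, adjusted p = 0.0175) and 3 of 7 members fell, while without WT replicate 1 its median was 0.17.

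Genes of ac4C writing and nucleolar ribosome biogenesis, the machinery Nat10 belongs to, did not shift as a list: none of 39 passed over all genes or the list alone, and the median was 0.04 (adjusted p = 0.491 by camera). Its smallest p-values were those of Nop56 (log2 1.68, SE 0.42) and Ltv1 (log2 0.88, SE 0.32). Translation factors had a median of 0.20, with 41 tested, none past the test, 1 higher adjusted over the list alone and an adjusted p of 0.0602 for the list. The list passed in 6 alternatives, with adjusted p-values of 0.0222 (DESeq2), 0.0301 (library quality weights), 0.0313 (exact test), 0.0403 (no filter), 0.0467 (CPM filter) and 0.0474 (limma-voom). Etf1, the translation termination factor gene, was at log2 1.06 (SE 0.22, adjusted p = 0.0601, edgeR) and Eif4g2 at 0.67 (SE 0.17). Only 29 of 85 cytosolic ribosomal protein genes had enough counts, reads they share with pseudogenes make those counts uncertain, and their median was 0.08, with none past either threshold (adjusted p = 0.838; Rpl7 -0.84, SE 0.36; Rps3a1 0.63, SE 0.28); without WT replicate 2 it was 0.43 (adjusted p = 0.0519). The lists of the integrated stress and unfolded protein responses (25 tested, median 0.00, adjusted p = 0.996; Pdia4 -0.71, SE 0.16; Pdia6 -0.46, SE 0.13) and of p53 targets (12 tested, median -0.01, adjusted p = 0.955; Ccng1 -1.15, SE 0.31) held no gene that passed; adjusted over the list alone, 1 stress gene fell. Phlda3, a p53 target with 2 counts in the cKO libraries together, was 22.7 times higher in WT (counting interval 6.01 to 192).

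**Figure D3:**
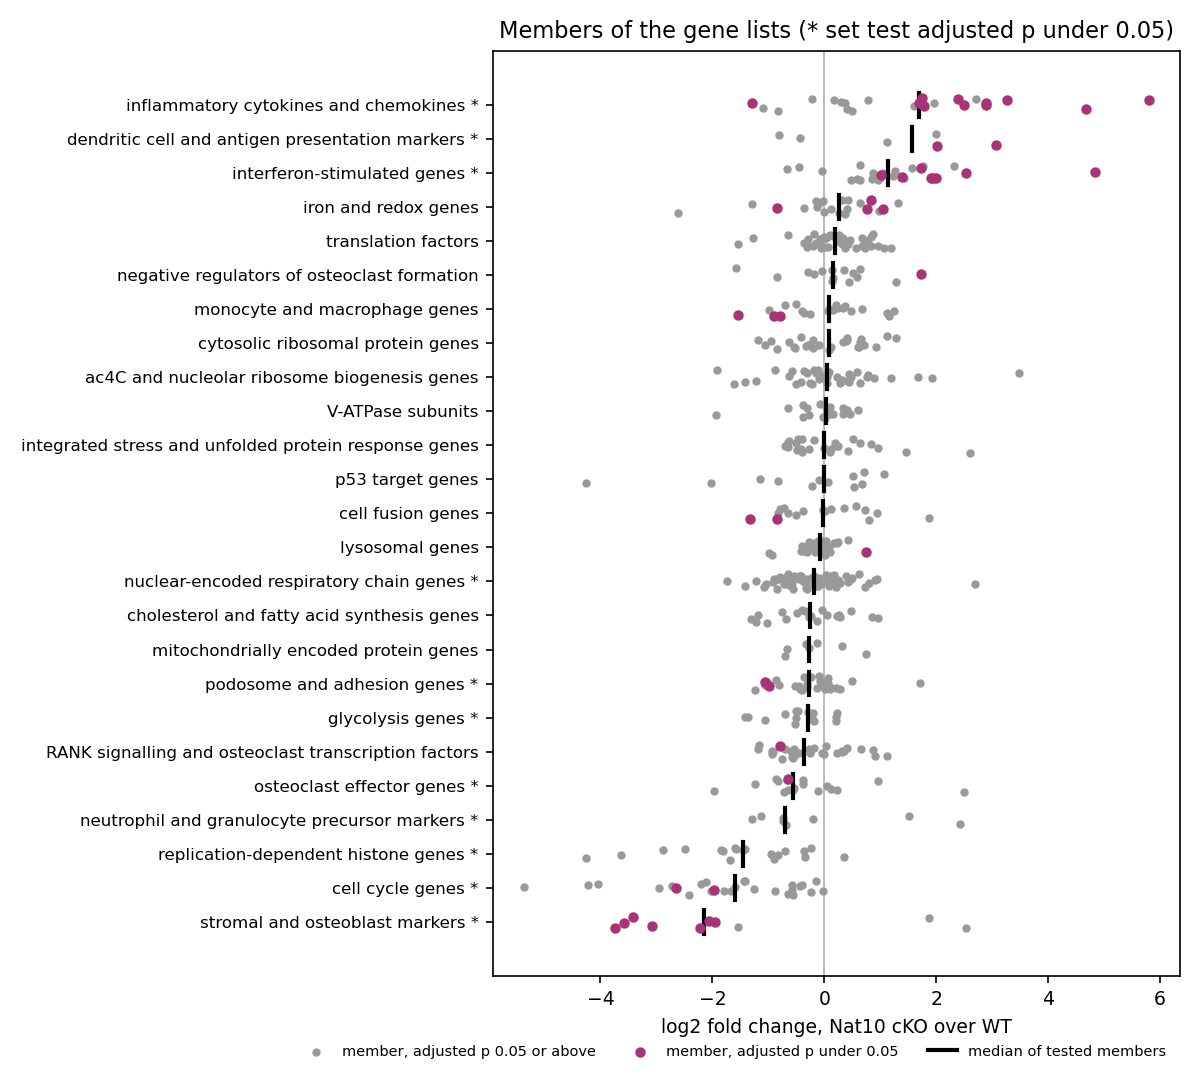
Log2 fold changes (Nat10 cKO over WT) of the tested members of the 25 gene lists with at least 5 tested members; each point is a gene, coloured where its adjusted p is under 0.05, and each bar is the list's median. Lists marked with an asterisk passed the set test, 3 of them higher (inflammatory, antigen presentation and interferon genes) and 8 lower, with stromal markers lowest at a median of -2.15.

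Few markers of other blood cell types had enough counts to be tested. Neutrophil and granulocyte precursor markers had a median of -0.71 (8 tested, none passed, 3 lower adjusted over the list alone, adjusted p = 0.0333 by camera, adjusted p = 0.308 with an estimated correlation), and the call was lost without WT replicate 1 (adjusted p = 0.252), cKO replicate 1 (0.0533) or cKO replicate 2 (0.113), with the replicate number as a block (0.0590), with limma-voom (0.0514) and with the CPM filter (0.0818). S100a9 (log2 -0.74, SE 0.18) and Ngp (log2 -1.29, SE 0.29) had the smallest p of these and did not pass. Of the B cell markers only 3 were tested and none passed, with 1 lower adjusted over the list alone. The immunoglobulin genes Ighm (2 and 5 counts in cKO, 21 and 78 in WT) and Igkc (3 and 6 against 12 and 63) had few counts. Il7r, the 1 tested gene of the T and NK cell list, was at log2 -0.32 (SE 0.36), and no gene of the erythroid, mast cell and basophil, or sex-linked lists had enough counts. Over the 25 lists tested, 11 passed camera's preset correlation, none passed with an estimated one, and 7 passed fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Of those 7, 6 were among the 11 and the other was the macrophage list. The form with an estimated correlation takes its degrees of freedom from the 4 libraries, so few lists could pass it. The stromal list's estimated correlation was -0.11, under the preset 0.01, and its adjusted p by that form of camera was still 0.165.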

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

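Thinning, library quality weights and their values were chosen after the data had been seen. All 51 higher and 60 lower genes kept their direction in every alternative that tested them, which their groups, none of which overlapped, made nearly certain. The number of genes past the threshold did change. Without a filter 184 were higher and 179 lower, with the CPM filter 95 and 95, with DESeq2 114 and 108 (3855 adjusted p-values were not given), with limma-voom 485 and 206, with edgeR's exact test 107 and 131, with quality weights 574 and 399, at an adjusted p under 0.1 87 and 92, and against a fold of 1.5 22 and 23; thinning gave 77 and 80. Leaving out 1 library gave 35 to 1354 higher and 38 to 1066 lower genes; the lone sample is then assumed to vary like the other group, and without either WT library the spread comes from the close cKO pair alone. The replicate numbers showed no sign of pairing the samples (correlation of their differences -0.02). With so unlike a WT pair, this does not exclude a pairing. The fit with the replicate block gave 67 and 76 genes and 10 lists, the granulocyte list being lost (adjusted p = 0.0590 by camera). Quality weights also brought in the RANK signalling (0.0442) and macrophage lists (0.00118), and DESeq2 that of negative regulators (0.0460). The lists past the set test numbered 0 with an estimated correlation, 7 by fry, 9 by camera on ranks, 8 to 12 without 1 library, 14 with DESeq2 and 15 with quality weights, against 11. Nat10 changed sign with quality weights (0.0026) and ranged from -0.51 to 0.25 without 1 library. Nfatc1 passed, which it did not in the main test, without a filter (-1.15, adjusted p = 0.0106), with the CPM filter (-1.15, 0.0431), with DESeq2 (-1.17, 0.0247), limma-voom (-1.19, 0.00403), the exact test (-1.17, 0.0113) and quality weights (-1.19, 0.000249), and ranged from -1.19 to -1.10 without 1 library; with the replicate block its adjusted p was 0.0883. Il7r ranged from -0.56 to 0.078 without 1 library, the latter without WT replicate 2. The cause was not tested for any of these. Of 1249 comparisons of 70 named genes, Nat10 and Nfatc1 not counted among them, 1062 kept side and direction, 121 newly passed, 65 no longer passed and 1 reversed. Of 448 comparisons for the lists, 422 stayed on the same side of the threshold, 14 newly passed, 12 no longer passed and 0 reversed. A list was counted as reversed only if it passed in either fit, so sign changes of lists that passed in neither are among the 422. Depth limits genes of few counts, and the low complexity of WT replicate 2 may limit their calls further, which was not tested.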

Other observations

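All tests in this part were chosen after the results they measure were seen, except that the dendritic cell and mesenchymal gene tests were written before their results. Their decision rules were tightened after the values were seen: an interval was required for the medians, a sum made up mostly of 1 gene was treated as undecided, and a gene shared with the stromal list was left out of the mesenchymal test. Under the rules as first written, the mesenchymal, granulocyte and dendritic cell tests each counted against their explanation. The values were a median of -0.32 over 9 mesenchymal genes, a median of -0.71 over 8 granulocyte markers (6 negative), and a dendritic sum ratio of 0.67. Those explanations stay open below only under the tightened rules.

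The deposited pathway annotation gave a wider view of the same contrast. Of 301 pathways tested with camera, 41 were higher and 7 lower in the libraries labelled Nat10 cKO. None passed with an estimated correlation, a form of the test that few sets can pass with so few libraries. NF-kappa B signaling (70 tested, median 0.23, adjusted p = 1.74e-09 by camera, adjusted p = 0.380 with an estimated correlation) and TNF signaling (75 tested, median 0.25, adjusted p = 1.27e-06) each had 11 members that rose, and 1 TNF signaling member, Mmp9, fell. Among genes outside the fixed lists, Cd40, a costimulatory receptor gene (log2 2.61, SE 0.31), Cd274, the gene of the checkpoint ligand PD-L1 (log2 1.29, SE 0.18), Acod1, the gene of the enzyme that makes itaconate (log2 0.78, SE 0.11), and Icam1, an adhesion molecule gene (log2 0.998, SE 0.17), rose. Proteasome genes were higher as a group without any member passing (42 tested, median 0.37, adjusted p = 0.00128 by camera, adjusted p = 0.397 with an estimated correlation). These genes were named after their values were seen.

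ECM-receptor interaction was the pathway with most genes that fell (43 tested, 12 fell, median -0.91, adjusted p = 5.05e-18 by camera, adjusted p = 0.380 with an estimated correlation), ahead of focal adhesion and PI3K-Akt signaling with 11 each, the latter not past the test (adjusted p = 0.0913). Single genes outside the fixed lists that fell, named after their values were seen, included Acta2, the smooth muscle actin gene (log2 -2.72, SE 0.21), Fn1, the fibronectin gene (log2 -2.08, SE 0.14), Timp1, a protease inhibitor gene (log2 -2.85, SE 0.29), Ccn2, the gene of connective tissue growth factor (log2 -2.82, SE 0.29), and Serpinh1, a collagen chaperone gene (log2 -2.76, SE 0.33). Lpl, the lipoprotein lipase gene (log2 -0.93, SE 0.11), and Siglec1, a sialic acid receptor gene (log2 -1.12, SE 0.14), also fell.

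The first pattern is the lower level of stromal and matrix genes in the libraries labelled cKO. The low complexity of WT replicate 2 alone is argued against, since without that library the list's median was still -2.29 and 8 of 11 members fell. Fewer stromal cells in those cultures may account for it and stays open. A list of mesenchymal receptor, adhesion and transcription factor genes had a median of -0.47 over 8 tested members, out of 28 in the count data. Pdgfrb, which the stromal list also holds, was left out (-0.32 over 9 with it). With so few members, the bounds for the median, -4.83 to 0.79, were simply the lowest and highest members, so the test could hardly decide. Of the 8, 6 were negative. Tested members such as Egfr (37 and 48 counts in cKO, 19 and 38 in WT) and Pdgfra (10 and 0 against 7 and 47) went opposite ways. Members with too few counts to be tested were mostly lower in cKO or without any count. Examples are Ptk7 (2 and 2 counts in cKO, 13 and 10 in WT) and Cavin1 (4 and 5 against 6 and 107). Among these untested members only Gli3 (0 and 1 against 0 and 0) went the other way. The member with most counts, Cav1, was at log2 -0.24 (SE 0.17). An effect of the genotype on matrix genes in the cells themselves was not tested and stays open too.

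The second pattern is the higher level of inflammatory and interferon genes. WT replicate 2 alone could not give it, since the inflammatory list's median without that library was 1.43, and less dilution of macrophage RNA by stromal RNA is argued against because the inflammatory median exceeded that of macrophage genes by 1.61 (two-sided permutation p = 0.00019 over genes, which are not independent replicates). More dendritic cells stay open: the lowest cKO sum of dendritic lineage genes was 0.67 times the highest WT sum, but Bst2, which macrophages also express and the interferon list also holds, made up at least 98.8% of it, and the other members had 8 and 11 counts in cKO and 4 and 1 in WT. Ccr7 alone gave 7 and 9 of those counts in cKO and 2 and 0 in WT, so the remaining lineage genes were almost without counts in every library. More granulocytes were not decided either, with a median of -0.71 over 8 markers. Its bounds, -1.29 to 2.42, were again the lowest and highest members, so this test could hardly decide. The abundant S100a8 (log2 -0.74, SE 0.20) and S100a9 were not higher. The 2 markers with a positive log2 fold change were Csf3r (65 and 20 counts in cKO, 8 and 8 in WT) and Mmp8 (61 and 35 against 19 and 10). An effect of the genotype, or a difference in activation between cultures, was not tested.

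The third pattern is that Nat10 counts were not measurably lower in the libraries labelled cKO. Loss of all Nat10 reads in all cells is argued against, because the lower 95% bound of the log2 fold change was -1.11, where such a loss would give -3 or less. A deletion of part of the gene, or in part of the cells, may leave most reads in place, and it cannot be told apart from no deletion here, since the upper bound was 0.74. The counts per gene hold no exon positions that would decide it, and a mislabelled library was not tested.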
